A study of Mus musculus with 6 samples.

How the data were processed

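Total RNA of wild-type mouse naive T, Th17 and Treg cells was extracted with a column kit for small inputs and made into libraries with a SMARTER mRNA kit, per the labels' protocols, and sequenced, with 2 libraries per type. The submitters' processing notes name cutadapt, STAR, DESeq2 and the genome build mm10, without versions. The release of the annotation, the counting tool and whether counting used strand are not given in the sources used here. The authors deposited 1 table of 54532 genes with whole-number counts per gene and library, not normalized, as its values show. Per the file headers it also holds log2 fold changes, p-values and adjusted p-values of the authors' comparisons of Th17 and Treg with naive cells, and gene length and coordinates. The log2 fold changes and p-values are printed only where they are named as the authors'. The table's 6 other columns of per-library values (FPKM) were not used. Of the table's genes, 98.3% have the coordinates of GENCODE release 21 for mouse, on GRCm38 (mm10), and coordinates are given as the table lists them, counted from 1. Column names carry the cell type and the numbers 1 and 5, while the sample titles carry 1 and 2, so columns were matched to types and not to single samples.

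Each type formed a group of 2 libraries, and the 3 comparisons among types came from 1 model over all 6 libraries with a mean per type and 3 residual degrees of freedom. Total counts ranged from 16458939 to 17901331, so a floor of 3 counts per library is about 0.201 CPM in naive, 0.161 in Th17 and 0.168 in Treg libraries; intervals and floors cover counting error only. Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, with limma 3.58.1 for the gene list tests, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are given as CPM computed by edgeR from the TMM-scaled library sizes. Values are given as mean ± SD over 2 libraries, and log2 fold changes with an approximate standard error (SE). This is the absolute log2 fold change divided by the square root of its F statistic, and it is rough for genes near 0 counts. Scaling by total count instead of TMM moves the median log2 fold change by 0.24 in Th17 and 0.18 in Treg against naive cells, and by -0.05 in Treg against Th17 cells. Changes are relative to the TMM scale. A gene at 0 counts in a group is given as at least N-fold higher or lower against the floor of 3 counts per library, and a gene with 1 to 3 counts in a group as a ratio with an exact 95% binomial interval.

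Fixed before the data were examined were the tests, the alternatives, 27 lists of genes and the rule for naming genes. The lists cover lineage signatures, metabolism, signalling and markers of other cell types, and 26 of them had at least 4 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over 78 tests, and beside it with an estimated correlation and with fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes. Of the 78 tests, 33 passed. With an estimated correlation 0 passed, and 8 did at an unadjusted p under 0.05, and fry passed 51. The estimate rests on 3 residual degrees of freedom, so that test has little power. Even the cell cycle list, with 28 of 28 members higher in Th17 than naive cells, did not pass it (camera adjusted p = 0.448). Not passing it therefore does not argue against a list, and it cannot tell whether the preset value is too low. The rule names fixed lineage and naive genes (among them Foxp3, Il2ra, Ctla4, Ikzf2, Il17a, Il17f, Il23r, Ccr7, Tcf7 and Lef1), the 6 genes with the largest change in each direction per comparison above the median expression and with non-overlapping libraries, up to 3 called members per list and direction, and the 6 genes and 6 long non-coding RNA genes that lead each type-specific set. Some genes that the rule names are not reported here. Genes named for other comparisons than the rule chose them in were chosen after their values were seen, as were the ribosomal and mitochondrial genes. A gene was specific to a type when it passed as higher than in both other types. These sets share libraries, so they were set beside simulated groups without an effect and beside the overlap of independent lists.

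The model was tested on simulated data with 200 of 15543 genes changed by known folds. At 2-fold, 42% of changed genes were recovered for Th17 against naive, 58% for Treg against naive and 42% for Treg against Th17 cells. At 8-fold the shares were 94%, 84% and 88%, with 9, 12 and 6 unchanged genes called. In the data far more genes were called (8973, 6748 and 5974 in the same order), which makes the adjusted threshold less strict. The simulation therefore does not measure recovery or false calls in the data. The replicates of each type differed by more than sampling noise (chi-square per degree of freedom 37.5, 19.6 and 16.6 for naive, Th17 and Treg), so each library counted once. The alternatives were DESeq2's size factors and scaling by total count, 2 other filters on low counts, DESeq2 1.42.0 and limma-voom, a fit per pair of types, each library left out in turn, a replicate block, and stricter thresholds.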

Results

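RNA was sequenced from wild-type mouse naive T cells, Th17 cells and regulatory T (Treg) cells, with 2 libraries per type and 6 in all. Naive T cells have not met antigen, Th17 cells are helper cells that secrete interleukin-17, and Treg cells restrain immune responses under the transcription factor Foxp3. The labels give thymus as the tissue of origin for every library. Whether Th17 and Treg cells were taken directly or made in culture, and with what stimulation, is not given in the sources used here, so any such difference is part of every difference between types below. The series title concerns a long non-coding RNA specific to Treg cells, so the comparisons ask what sets each type apart from the others, long non-coding RNAs included. The deposited table numbers the libraries of each type 1 and 5. Total counts were 16458939 and 16569280 in naive libraries 1 and 5, 17491083 and 17395469 in Th17 libraries and 16877130 and 17901331 in Treg libraries, and 15543 genes had enough counts to be tested. The labels do not say that the libraries of a type came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of the same type correlated at r = 0.982 for naive, 0.986 for Th17 and 0.986 for Treg across genes (log2 CPM, genes not being independent replicates), and libraries of different types at 0.796 to 0.890. The first principal component held 64.1% of the variance and placed Treg between naive and Th17. The second held 28.1% and set Treg apart from both.

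The lineage genes separated the types. Foxp3 (chromosome X, 7579676 to 7595243, mm10) stood at 1009 ± 0.0335 CPM in Treg cells (SD, n = 2), 14.3 ± 1.11 CPM in naive cells and 0.697 ± 0.302 CPM in Th17 cells. Il17a, which encodes interleukin-17A, reached 330 and 500 CPM in the Th17 libraries and had 0 counts in all naive and Treg libraries, so it was at least 2070-fold higher in Th17 than in naive cells and at least 2477-fold higher than in Treg cells, against a floor of 3 counts per library. Il17f averaged 2205 ± 4.68 CPM in Th17 cells, with 8 counts over both naive libraries and 1 count over both Treg libraries. The receptor gene Il23r averaged 13.0 ± 1.33 CPM in Th17 cells, with 3 counts in naive and 1 in Treg libraries.

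**Figure D1:**
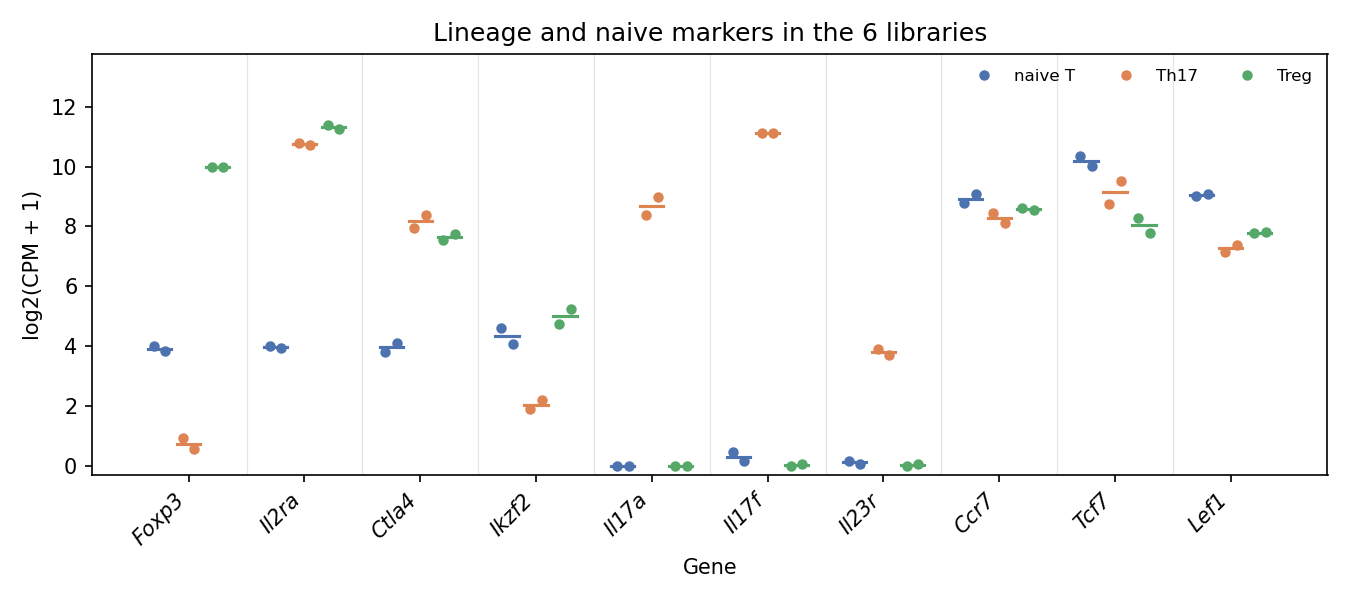
Level of 10 lineage and naive T cell genes, as log2(CPM + 1) on the vertical axis, in each of the 6 libraries; points are libraries, coloured by cell type, and bars are means of 2 libraries. Foxp3 lies highest in Treg libraries and Il17a, Il17f and Il23r in Th17 libraries.

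Th17 cells against naive cells. The comparison asks which genes distinguish Th17 from naive cells. Th17 cells carried the interleukin-17 programme and high levels of cell division, lipid synthesis and glycolysis genes, and lower levels of naive-state, interferon-stimulated and T cell receptor genes. These list calls did not pass camera with an estimated correlation (adjusted p = 0.367 to 0.547), a test of little power here. Il2ra, the high-affinity interleukin-2 receptor chain, rose from 14.8 ± 0.423 CPM to 1715 ± 71.6 CPM (log2 fold change 6.86 ± 0.26 (SE), adjusted p = 6.7e-11). Lef1 fell (log2 fold change -1.78 ± 0.17 (SE), adjusted p = 5.9e-07), as did Ikzf2 (log2 fold change -2.63 ± 0.29 (SE), adjusted p = 2.4e-06) and Foxp3 (log2 fold change -4.34 ± 0.28, adjusted p = 9.7e-09). The checkpoint gene Ctla4 rose by a log2 fold change of 4.29 ± 0.21 (adjusted p = 7.5e-10). Il17f passed at adjusted p = 2.1e-11, Il17a at 1.7e-10 and Il23r at 8.5e-08, where Il23r was 130-fold (95% counting interval 44.1 to 630) higher. In all, 4557 genes were higher and 4416 lower in Th17 cells, and 6105 of these changed at least 2-fold. With libraries scaled by total count alone, 62.6% of the calls were higher instead of 50.8%.

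In the Th17 signature, 17 of 20 measured members were higher and 3 lower (the same adjusted over the list alone; median log2 fold change 6.89, or 6.72 with members at 0 counts in a group set to their bound; camera adjusted p = 7.3e-08, and adjusted p = 0.367 with an estimated correlation). The chemokine gene Ccl20, at 77.6 and 37.9 CPM in Th17 libraries 1 and 5 and 0 counts in naive libraries, was at least 288-fold higher on their mean, and Il21 was higher by a log2 fold change of 6.87 ± 0.27. The 3 lower members were Il6st (-1.96 ± 0.21), Runx1 (-0.48 ± 0.16) and Nfkbiz (-0.50 ± 0.16). The Runx1 and Nfkbiz calls ended with scaling by total count (adjusted p = 0.229 and 0.207) and without naive library 1 or either Th17 library. In the Treg signature, 13 of 23 measured members were higher and 7 lower (the same adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.183, and adjusted p = 0.604 with an estimated correlation). Il10, which encodes an anti-inflammatory cytokine, averaged 38.7 ± 21.4 CPM in Th17 cells and 0.242 ± 0.342 CPM in naive cells (adjusted p = 4.2e-07), and Ebi3 was 461-fold (95% counting interval 127 to 3810) higher. Izumo1r (-4.35 ± 0.18) and Prdm1 (-3.63 ± 0.52) fell. In the naive and quiescence list, 2 of 20 measured members were higher and 16 lower (the same adjusted over the list alone; camera adjusted p = 1.0e-04, and adjusted p = 0.367 with an estimated correlation). Dapl1 (-8.91 ± 0.33) and the quiescence factor Klf2 (-6.47 ± 0.23) fell, while Bach2 (0.97 ± 0.20) and Satb1 (0.94 ± 0.19) rose. T cell activation genes went both ways: 11 of 20 measured members were higher and 7 lower (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.413, and adjusted p = 0.752 with an estimated correlation). Irf4 rose (5.46 ± 0.22), and Egr3 (-3.59 ± 0.25), Egr1 (-2.29 ± 0.20) and Cd40lg (-2.08 ± 0.20) fell.

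Cell division and biosynthesis genes rose together. In the cell cycle list, 28 of 28 measured members were higher and 0 lower (the same adjusted over the list alone; median log2 fold change 5.45; camera adjusted p = 2.2e-12, and adjusted p = 0.448 with an estimated correlation), led by Ube2c (8.31 ± 0.34), Aurkb (7.97 ± 0.29) and Ccnb1 (7.60 ± 0.34). In cholesterol and fatty acid synthesis, 25 of 25 measured members were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 5.5e-09, and adjusted p = 0.448 with an estimated correlation), with the desaturase genes Scd2 (4.96 ± 0.28) and Scd1 (4.61 ± 0.24) at the top. In glycolysis, where Aldoa is counted under 2 gene identifiers, 16 of 20 measured members were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 3.1e-05, and adjusted p = 0.367 with an estimated correlation). The hexokinase gene Hk2 (6.69 ± 0.26) and the lactate exporter gene Slc16a3 (4.43 ± 0.23) rose. In amino acid transport and serine synthesis, 16 of 20 measured members were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 2.6e-05, and adjusted p = 0.448 with an estimated correlation). The asparagine synthetase gene Asns rose (9.17 ± 0.38), and Chac1, with 0 counts in naive libraries, was at least 72.3-fold higher. Oxidative phosphorylation genes mostly stayed short of the threshold: 2 of 28 measured members were higher and 5 lower (2 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.857, and adjusted p = 0.973 with an estimated correlation).

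Interferon-stimulated genes fell. In that list, 0 of 25 measured members were higher and 21 lower (the same adjusted over the list alone; median log2 fold change -4.24; camera adjusted p = 5.0e-08, and adjusted p = 0.448 with an estimated correlation). Oas2 (-8.08 ± 0.57) and Ifit3 (-6.78 ± 0.41) fell, and Rsad2 was 440-fold (95% counting interval 78.4 to 17414) higher in naive cells. The interferon-inducible genes Ifi213 and Ifi208, at 328 ± 22.0 CPM and 182 ± 3.02 CPM in naive cells, had 0 counts in Th17 libraries, so they were at least 2038-fold and at least 1128-fold lower. Both belong to a cluster of closely related genes, so the split of reads among its members is uncertain. In the T cell receptor complex, 2 of 18 measured members were higher and 12 lower (the same adjusted over the list alone; camera adjusted p = 0.00824, and adjusted p = 0.547 with an estimated correlation). Cd247 (-2.54 ± 0.19), Trbc2 (-2.49 ± 0.23) and Cd3g (-2.19 ± 0.22) fell and Cd5 rose (0.83 ± 0.19). Most B cell, myeloid and dendritic, and NK and gamma-delta markers tested were lower than in naive libraries. Of the 14 NK and gamma-delta genes listed, 8 were tested. Among B cell markers, 0 of 14 measured members were higher and 13 lower (the same adjusted over the list alone; camera adjusted p = 1.7e-06, and adjusted p = 0.367 with an estimated correlation). Among myeloid and dendritic markers, 2 of 18 measured members were higher and 13 lower (the same adjusted over the list alone; camera adjusted p = 0.00239, and adjusted p = 0.448 with an estimated correlation), and Cd74 was an exception (74.2 ± 21.9 CPM in naive and 166 ± 6.61 CPM in Th17 cells). Among NK and gamma-delta markers, 1 of 8 measured members was higher and 7 lower (the same adjusted over the list alone; camera adjusted p = 0.00202, and adjusted p = 0.448 with an estimated correlation), with Klre1 the higher member (2.44 ± 0.48). Among immediate early and heat shock genes, 5 of 20 measured members were higher and 11 lower (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0852, and adjusted p = 0.752 with an estimated correlation). The fall of Tcf7 (-1.01 ± 0.25, adjusted p = 0.00332) ended without Th17 library 1 (adjusted p = 0.0563), and that of Ccr7 (-0.64 ± 0.18, adjusted p = 0.00750) ended without Th17 library 5 (adjusted p = 0.110) and with scaling by total count (adjusted p = 0.0714).

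**Figure D2:**
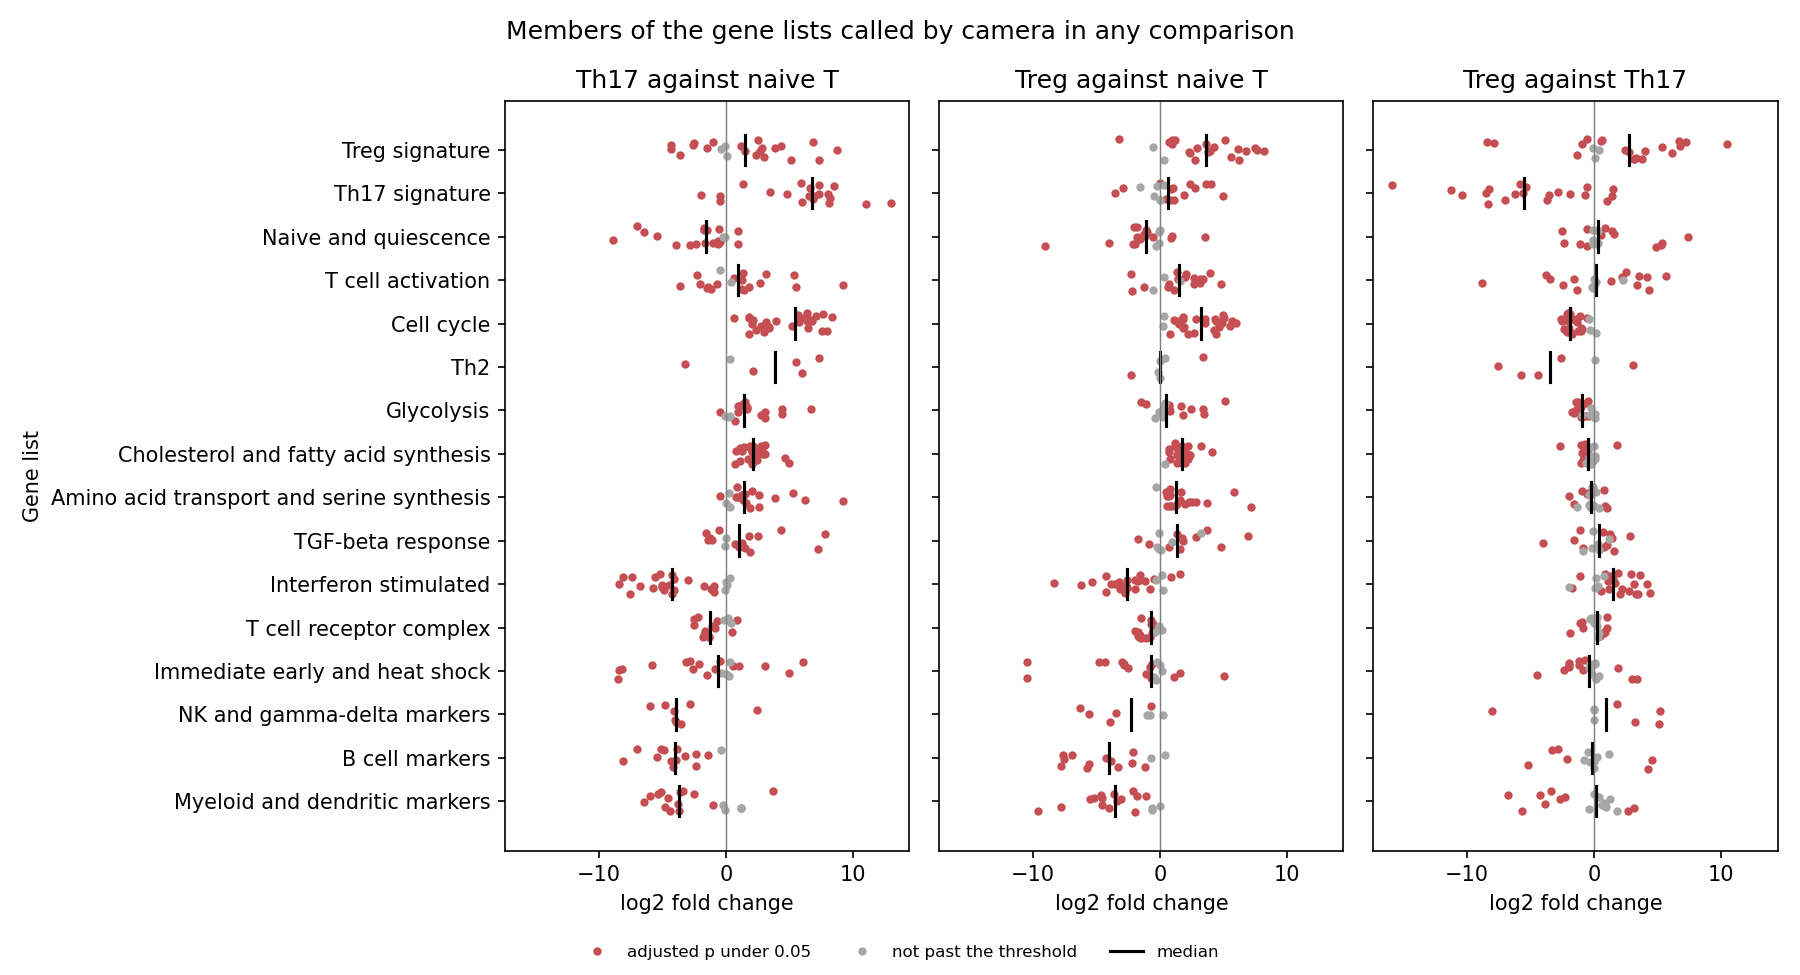
Log2 fold changes on the horizontal axis of the members of the gene lists called by camera in at least 1 comparison, with 1 row per list and 1 panel per comparison; points are genes, red where adjusted p is under 0.05, black bars are list medians, and genes at 0 counts in a group are drawn at their bound. All 28 cell cycle genes lie above 0 in Th17 against naive cells, and 25 of them passed as lower in Treg than in Th17 cells.

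Treg cells against naive cells. The comparison asks which genes distinguish Treg from naive cells. Treg cells carried Foxp3 and most of the Treg signature, with higher cell cycle, lipid and amino acid genes, and lower interferon-stimulated and T cell receptor genes. These list calls did not pass camera with an estimated correlation (adjusted p = 0.367 to 0.448), a test of little power here. Foxp3 rose (log2 fold change 6.14 ± 0.22 (SE), adjusted p = 9.5e-11), as did Il2ra (log2 fold change 7.43 ± 0.26 (SE), adjusted p = 9.5e-11) and Ctla4 (log2 fold change 3.76 ± 0.21, adjusted p = 4.7e-09). Tcf7 (-2.13 ± 0.26, adjusted p = 1.3e-05) and Lef1 (-1.26 ± 0.17, adjusted p = 2.8e-05) fell. Ccr7 did not pass (log2 fold change -0.36 ± 0.18, adjusted p = 0.123), nor did Il23r (adjusted p = 0.335) or Il17a, at 0 counts in both types. In all, 3662 genes were higher and 3086 lower in Treg cells, and 4167 of these changed at least 2-fold. With libraries scaled by total count alone, 67.0% of the calls were higher instead of 54.3%. Without Treg library 1, 1827 genes were lower.

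In the Treg signature, 20 of 23 measured members were higher and 1 lower (20 and 2 adjusted over the list alone; median log2 fold change 3.60; camera adjusted p = 5.5e-09, and adjusted p = 0.367 with an estimated correlation). Socs2 (8.21 ± 0.39), the integrin gene Itgae (7.60 ± 0.32), Lrrc32, which encodes the TGF-beta docking receptor GARP (6.72 ± 0.25), Nrp1 (6.17 ± 0.21) and Gpr83 (4.20 ± 0.21) rose, and Prdm1 was the lower member (-3.27 ± 0.51). Il10 had 0 counts in both Treg libraries. The rise of Ikzf2, which encodes Helios, was small (0.67 ± 0.25, adjusted p = 0.0445) and ended without naive library 5 (adjusted p = 0.269) or Treg library 5 (adjusted p = 0.367) and with DESeq2 (adjusted p = 0.0511). In the Th17 signature, 12 of 20 measured members were higher and 2 lower (12 and 3 adjusted over the list alone; camera adjusted p = 0.0244, and adjusted p = 0.580 with an estimated correlation). Ccl20, at 0 counts in naive libraries, was at least 5.05-fold higher. The 2 lower members were Il21, at least 11.6-fold lower, and Il17f, with 8 counts against 1, a ratio of 9.56-fold (95% counting interval 1.28 to 424). The Il17f call ended with DESeq2 (adjusted p = 0.0759), limma-voom (0.0585) and scaling by total count (0.0587), and without naive library 1 (0.278) or Treg library 1 (0.263) or 5 (0.0831). In the activation list, 14 of 20 measured members were higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.00555, and adjusted p = 0.448 with an estimated correlation). Irf8 (4.82 ± 0.20), Irf4 (3.91 ± 0.21), Pdcd1 (3.37 ± 0.20), Nr4a3 (3.16 ± 0.18), Egr2 (2.63 ± 0.24) and Egr3 (2.04 ± 0.21) rose, and Cd40lg (-2.26 ± 0.20), Batf (-2.21 ± 0.18) and Cd69 (-1.29 ± 0.16) fell. In the TGF-beta response list, 9 of 17 measured members were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.00925, and adjusted p = 0.547 with an estimated correlation), with Bhlhe40 (6.91 ± 0.24) and Pmepa1 (4.76 ± 0.24) at the top. In the naive and quiescence list, 3 of 20 measured members were higher and 13 lower (the same adjusted over the list alone; camera adjusted p = 0.00103, and adjusted p = 0.367 with an estimated correlation). The interleukin-7 receptor gene Il7r fell (-4.01 ± 0.26), and Ccr9 (3.50 ± 0.25), Bach2 (0.90 ± 0.20) and Foxp1 (0.85 ± 0.16) rose.

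Among the genes with the largest rises, Lcn10, a lipocalin gene, averaged 99.4 ± 4.64 CPM in Treg cells against 0 counts in naive libraries (at least 495-fold higher), and Stxbp6 was at least 315-fold higher. The carboxypeptidase gene Cpd rose from 0.394 ± 0.264 CPM to 298 ± 37.2 CPM (9.51 ± 0.35). In the cell cycle list, 26 of 28 measured members were higher and 0 lower (the same adjusted over the list alone; median log2 fold change 3.18; camera adjusted p = 1.1e-11, and adjusted p = 0.448 with an estimated correlation). In cholesterol and fatty acid synthesis, 24 of 25 measured members were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 5.5e-09, and adjusted p = 0.448 with an estimated correlation), with Scd1 (4.09 ± 0.24) and the elongase gene Elovl6 (3.20 ± 0.22) at the top. In amino acid transport and serine synthesis, 19 of 20 measured members were higher and 0 lower (the same adjusted over the list alone; camera adjusted p = 8.5e-07, and adjusted p = 0.448 with an estimated correlation), Asns among them (7.15 ± 0.39). In glycolysis, 10 of 20 measured members were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.0157, and adjusted p = 0.380 with an estimated correlation). Hk2 rose (5.10 ± 0.26) and Slc2a3 fell (-1.08 ± 0.25). Gapdh also fell (-1.51 ± 0.20), a value made uncertain by its many processed pseudogenes. In oxidative phosphorylation, 1 of 28 measured members was higher and 2 lower (1 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.744, and adjusted p = 0.972 with an estimated correlation).

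Interferon-stimulated genes fell here too: 2 of 25 measured members were higher and 20 lower (the same adjusted over the list alone; median log2 fold change -2.61; camera adjusted p = 1.0e-06, and adjusted p = 0.448 with an estimated correlation). Oas2 (-5.34 ± 0.45) fell, and Gbp3 (1.57 ± 0.23) and Stat2 (0.84 ± 0.17) rose. In the T cell receptor complex, 0 of 18 measured members were higher and 14 lower (0 and 15 adjusted over the list alone; camera adjusted p = 5.2e-05, and adjusted p = 0.448 with an estimated correlation), with Cd3g (-1.95 ± 0.22), Trbc2 (-1.76 ± 0.22) and Trac (-1.73 ± 0.19) lowest. Among immediate early and heat shock genes, 3 of 20 measured members were higher and 12 lower (3 and 13 adjusted over the list alone; camera adjusted p = 6.8e-04, and adjusted p = 0.536 with an estimated correlation). Hspa1b averaged 1743 ± 101 CPM in naive and 1.24 ± 0.674 CPM in Treg cells, and Fos fell (-4.83 ± 0.19); Hspa1a and Hspa1b are near-identical, so the split of reads between them is uncertain. Atf3 rose (5.02 ± 0.43). Most B cell, myeloid and dendritic, and NK and gamma-delta markers tested were again lower than in naive libraries. The lists of CD8 T cell, immature thymocyte, thymic epithelial and stromal, and red cell markers did not pass camera. Among B cell markers, 0 of 14 measured members were higher and 12 lower (the same adjusted over the list alone; camera adjusted p = 2.4e-07, and adjusted p = 0.367 with an estimated correlation). Among myeloid and dendritic markers, 0 of 18 measured members were higher and 15 lower (1 and 15 adjusted over the list alone; camera adjusted p = 3.3e-07, and adjusted p = 0.367 with an estimated correlation), and Cd74 fell from 74.2 ± 21.9 CPM to 3.16 ± 0.0917 CPM. Among NK and gamma-delta markers, 0 of 8 measured members were higher and 5 lower (the same adjusted over the list alone; camera adjusted p = 0.00239, and adjusted p = 0.448 with an estimated correlation).

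Treg cells against Th17 cells. The comparison asks how the types other than naive differ from each other. Treg cells had more Foxp3, more of the Treg signature and more interferon-stimulated transcripts, and fewer interleukin-17, cell cycle and glycolysis transcripts. These list calls did not pass camera with an estimated correlation (adjusted p = 0.367 to 0.536), a test of little power here. Foxp3 was higher in Treg cells (log2 fold change 10.48 ± 0.29 (SE), adjusted p = 1.7e-11), as was Ikzf2 (log2 fold change 3.30 ± 0.29 (SE), adjusted p = 5.7e-07). Il17f passed at adjusted p = 1.7e-11, Il17a at 4.6e-10 and Il23r, 465-fold (95% counting interval 83.0 to 18389) lower in Treg cells, at 9.4e-08. Ccr7 did not pass (0.28 ± 0.18, adjusted p = 0.245). In all, 2957 genes were higher and 3017 lower in Treg cells, and 3680 of these changed at least 2-fold. Without Th17 library 1, 1961 genes were higher. The smaller differences of Il2ra (0.57 ± 0.20, adjusted p = 0.0338), Ctla4 (-0.53 ± 0.18, adjusted p = 0.0336), Lef1 (0.52 ± 0.17, adjusted p = 0.0227) and Tcf7 (-1.12 ± 0.25, adjusted p = 0.00287) each ended with at least 1 library left out, at adjusted p = 0.214, 0.255 and 0.115 without Treg library 1 and 0.0573 for Tcf7 without Treg library 5.

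In the Treg signature, 15 of 23 measured members were higher and 5 lower (the same adjusted over the list alone; median log2 fold change 2.72; camera adjusted p = 2.1e-04, and adjusted p = 0.367 with an estimated correlation), with Nrp1 (7.23 ± 0.22), Gpr83 (6.74 ± 0.25), Lrrc32 (6.68 ± 0.24) and Itgae (6.08 ± 0.29) higher. Il10, at 53.9 and 23.6 CPM in Th17 libraries 1 and 5 and 0 counts in Treg libraries, was at least 231-fold lower on their mean, Ebi3 was 367-fold (95% counting interval 125 to 1784) lower, and Icos was lower (-1.38 ± 0.17). In the Th17 signature, 3 of 20 measured members were higher and 17 lower (the same adjusted over the list alone; median log2 fold change -5.51; camera adjusted p = 5.5e-09, and adjusted p = 0.367 with an estimated correlation). Il21 was at least 1372-fold lower. Il6st (1.45 ± 0.20), Runx1 (1.36 ± 0.16) and Nfkbiz (0.99 ± 0.16) were higher. In the cell cycle list, 0 of 28 measured members were higher and 25 lower (the same adjusted over the list alone; median log2 fold change -1.88; camera adjusted p = 5.5e-09, and adjusted p = 0.522 with an estimated correlation), with Ccnb1 (-2.61 ± 0.24), Aurka (-2.56 ± 0.22) and Ube2c (-2.37 ± 0.22) lowest. In glycolysis, 0 of 20 measured members were higher and 15 lower (the same adjusted over the list alone; camera adjusted p = 3.1e-05, and adjusted p = 0.367 with an estimated correlation), with Hk2 (-1.59 ± 0.18) and Pgam1 (-1.48 ± 0.17) lower. In cholesterol and fatty acid synthesis, 1 of 25 measured members was higher and 13 lower (the same adjusted over the list alone; camera adjusted p = 0.00530, and adjusted p = 0.752 with an estimated correlation), with Scd2 lower (-2.68 ± 0.26) and Elovl6 higher (1.79 ± 0.21). No oxidative phosphorylation gene passed edgeR's test: 0 of 28, with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Among interferon-stimulated genes, 18 of 25 measured members were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 3.7e-05, and adjusted p = 0.536 with an estimated correlation). Ifit3 (4.15 ± 0.43) and Oasl2 (3.58 ± 0.50) were higher and Oas3 (-1.74 ± 0.32) and Bst2 (-1.13 ± 0.19) lower. In the Th2 list, 1 of 6 measured members was higher and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.0223, and adjusted p = 0.448 with an estimated correlation). Il9 (46.3 and 15.9 CPM in Th17 libraries 1 and 5) and Il24, at 0 counts in Treg libraries, were at least 185-fold and at least 54.7-fold lower on the mean of the Th17 libraries, and Gata3 was higher (3.03 ± 0.30). Only 6 of the 12 genes of the Th2 list were tested. Activation genes split: 8 of 20 measured members were higher and 6 lower (9 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.364, and adjusted p = 0.752 with an estimated correlation). Egr3 (5.63 ± 0.26), Nr4a3 (4.35 ± 0.20) and Egr2 (4.12 ± 0.26) were higher, and Batf was lower (-3.48 ± 0.18), as was Tnfrsf8, by 506-fold (95% counting interval 173 to 2456). The chemokine gene Xcl1 and Adamtsl2, at 0 counts in Th17 libraries, were at least 746-fold and at least 473-fold higher, and the adhesion molecule gene Epcam averaged 74.6 ± 8.39 CPM in Treg cells against 1 count over both Th17 libraries.

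Genes specific to a type. 1101 genes were higher in Treg cells than in both other types, against 2405 for Th17 and 2376 for naive cells. Of these, 81, 110 and 206 were long non-coding RNA genes among the 1400 tested. Simulated groups with no effect gave at most 1 gene in each of these counts in 20 simulations. Such groups hold few calls to overlap, so they do not measure what shared libraries add among many calls. Independent lists of the same sizes gave 697, 885 and 877, and part of the excess can come from the shared libraries. Protein-coding genes that led the Treg set were Lcn10, Stxbp6, Akr1c18 (8.85 ± 0.30 against Th17 and 8.01 ± 0.29 against naive cells), Xcl1, Adamtsl2 and Lrrc32. The naive set was led by Dapl1, Hspa1b, Hspa1a, Ifi208, Ifi213 and Dtx1, a Notch pathway gene (266 ± 33.0 CPM in naive, 3.59 ± 0.00918 CPM in Th17 and 3.98 ± 0.608 CPM in Treg cells). The Th17 set was led by Il17a, Ermn, Ltb4r1, Il17f, Pdpn and the kinase gene Alpk2 (9.40 ± 0.30 against naive cells). Ltb4r1, which encodes a leukotriene B4 receptor, had 0 counts in naive and Treg libraries and was at least 306-fold and at least 366-fold higher. Without Treg library 1, 1477 genes were specific to naive cells.

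Long non-coding RNAs specific to Treg cells were led by Gm35037 (ENSMUSG00000107985; chromosome 7, 3451357 to 3475020), at 6.24 and 8.62 CPM in Treg libraries 1 and 5 and 0 counts in the other 4 libraries, which makes it at least 37.0-fold higher than in naive and at least 46.2-fold higher than in Th17 cells (adjusted p = 3.8e-06 and 3.0e-06). It overlaps no other gene of the deposited annotation and lies 11480 bp from Tarm1. A630091E08Rik (ENSMUSG00000055446; chromosome 7, 98543320 to 98562990) averaged 4.60 ± 0.359 CPM in Treg cells, with 1 count over the other libraries, and Gm41414 (ENSMUSG00000116029; chromosome 16, 5306801 to 5450664) averaged 4.39 ± 1.96 CPM, also with 1 count elsewhere, and overlaps the ribosomal RNA gene n-R5s30 on the opposite strand. 2610204G07Rik (ENSMUSG00000084860; chromosome 13, 104684931 to 104694994) averaged 15.6 ± 3.80 CPM and lies antisense to Cwc27. Gm12224 (ENSMUSG00000085888; chromosome 11, 54340369 to 54353479) averaged 2.43 ± 0.200 CPM and lies antisense to Acsl6, itself at 133 ± 1.58 CPM in Treg cells. The sources used here do not state that counting used strand, so reads of these overlapping genes are not certain to be assigned to the right gene. Gm10384 (ENSMUSG00000072618; chromosome 15, 36870501 to 36879816) was at 0.687 and 2.51 CPM in Treg libraries and 0 counts elsewhere, and DESeq2 did not call it (adjusted p = 0.245 against naive and 0.243 against Th17 cells). Flicr, a non-coding RNA known to act on Foxp3 and overlapping that gene on the same strand, was higher in Treg than in naive (log2 fold change 1.82 ± 0.35 (SE), adjusted p = 7.8e-04) and Th17 cells (log2 fold change 4.39 ± 0.43 (SE), adjusted p = 1.6e-06); its reads are not certain to be separable from those of Foxp3. Mir155hg, the host gene of the microRNA miR-155, was higher in both Th17 (log2 fold change 6.54 ± 0.34 (SE), adjusted p = 1.1e-09) and Treg cells (log2 fold change 4.75 ± 0.35 (SE), adjusted p = 6.9e-08) than in naive cells. In Th17 cells, Gm29101 and Gm36070 averaged 6.30 ± 0.401 CPM and 17.1 ± 2.55 CPM. Gm29101 overlaps the protein-coding gene Twist2 on the same strand, so its reads are not certain to be separable from those of Twist2. In naive cells, A530021J07Rik and Mirt1 averaged 20.4 ± 4.95 CPM and 38.0 ± 14.7 CPM. They overlap 5930435M05Rik and 4833407H14Rik on the opposite strand, both also in the naive set, so the same limit on strand holds for them.

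**Figure D3:**
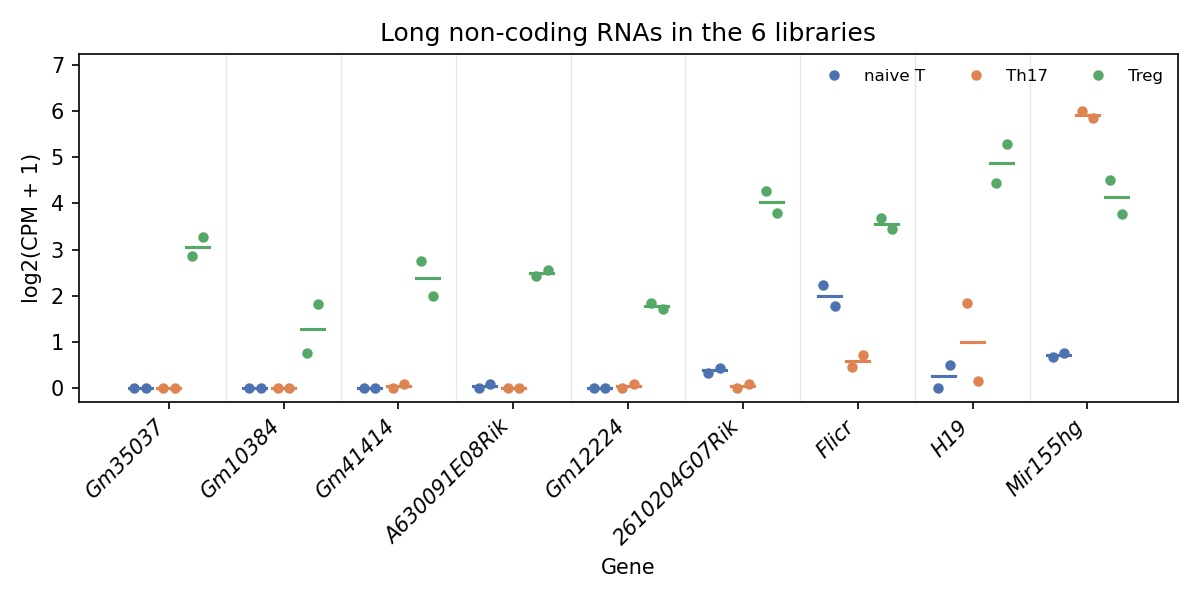
Level of the 6 long non-coding RNA genes that led the Treg set and of Flicr, H19 and Mir155hg, as log2(CPM + 1) on the vertical axis, in each of the 6 libraries; points are libraries, coloured by cell type, and bars are means of 2 libraries. Gm35037 has 0 counts in the naive and Th17 libraries, and Mir155hg lies highest in Th17 libraries.

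Changes shared by Th17 and Treg cells. 2601 genes were higher and 2376 lower in both types than in naive cells. Simulated groups without an effect, which hold few calls to overlap, gave at most 1 gene, and independent lists of the same sizes gave 1074 and 877. Both comparisons use the same naive libraries, so part of the excess over independent lists can come from these. Chac1, Asns, Hk2, Bhlhe40, Il2ra, Irf4 and Cpd were among the shared rises, and Dapl1, Hspa1b, Fos, Oas2, Cd3g and Slamf6 among the shared falls. The authors' deposited table compares Th17 and Treg with naive cells. At an adjusted p under 0.05 it lists 4223 genes as higher and 3460 as lower in Th17 cells, of which 4134 and 3362 were called in the same direction here. In the authors' deposited table, 3171 genes were higher and 2512 lower in Treg cells, of which 3122 and 2422 were called in the same direction here, and 0 genes were called in opposite directions in either comparison. For Foxp3, the authors' deposited table gives a log2 fold change of 6.17 in Treg cells.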

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

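Every alternative here was planned. Counts of calls stayed within 1.5 times under both other scalings, both other filters, DESeq2, limma-voom, a fit per pair of types and the replicate block. Within that band, scaling by total count left 1667 instead of 2376 genes specific to naive cells. It also gave 2235 instead of 3086 genes lower in Treg than naive cells, and 3397 instead of 2601 higher in both types than naive. Stricter thresholds lowered them by construction. The genes lower in Th17 than naive, higher and lower in Treg than naive, higher and lower in Treg than Th17, specific to naive, Th17 and Treg, and higher in both types than naive (lower in both is the naive-specific set) numbered 2885, 2270, 1556, 1562, 1785, 1190, 1455, 620 and 1559 against a fold of 1.5, and 2929, 2396, 1771, 1717, 1963, 1326, 1559, 677 and 1651 at a 2-fold minimum. At an adjusted p under 0.01, 1973 genes were lower in Treg than naive and 1502 were specific to naive cells. With each library left out in turn, the ranges were 3835 to 4572 and 3295 to 4305 (higher and lower in Th17 than naive), 2786 to 3605 and 1827 to 2976 (Treg than naive), 1961 to 3265 and 2066 to 3285 (Treg than Th17), 1477 to 2215, 1707 to 2432 and 735 to 1122 (naive, Th17 and Treg sets), 2079 to 2461 (higher in both) and 32 to 36 list tests; the lone library left in a group is then assumed to vary like the others. The lowest came without Treg library 1 for 1827 lower in Treg than naive and 1477 specific to naive cells, and without Th17 library 1 for 1961 higher in Treg than Th17 cells. Over all genes, columns of the same number shared little deviation from their type's mean (correlations 0.00466, 0.126 and 0.0334), while ribosomal protein genes were higher in library 5 in all 3 types; the replicate block gave 4649 and 4467 calls for Th17 and 3775 and 3199 for Treg against naive, and 33 list tests. Of 78 list tests, camera called 33 at the preset correlation and 0 with an estimated correlation, and fry called 51, of which 32 are among the 33. The test with an estimated correlation had little power. The Tfh list against naive in Th17 cells turned from up (camera adjusted p = 0.906) to down under fry (adjusted p = 0.00965); the cause was not tested. Hbb-bs turned to a log2 fold change of -4.25 without Th17 library 1, which holds all its Th17 counts, and ranged up to 5.74 with another library left out. This call ended too, but as a reversed one it is not among the 20 given below for Th17 library 1. DESeq2 ended 28 named calls, scaling by total count 13, and leaving out a library (1 and 5 in turn) 13 and 13 for naive, 20 and 21 for Th17 and 24 and 27 for Treg cells. At 2-fold, 42% to 58% of simulated changes were recovered.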

Other observations

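Tests chosen only after the result was seen are the scaling test of the ribosomal protein genes and their test against genes no longer than they are, the depth test of the marker genes and the test of summed Hspa1a and Hspa1b counts; the ribosomal and mitochondrial gene classes were also chosen after their values were seen. Helper cell genes outside the leading lists were mixed. In the Th1 list, 4 of 12 measured members were higher and 8 lower (the same adjusted over the list alone) in Th17 and 4 of 12 measured members were higher and 3 lower (4 and 4 adjusted over the list alone) in Treg against naive cells. Tbx21, the Th1 regulator, was higher in Treg than in naive cells (2.56 ± 0.39), as was the granzyme gene Gzmb (2.45 ± 0.31). In the Tfh list, 4 of 8 measured members were higher and 3 lower (5 and 3 adjusted over the list alone) in Th17 against naive cells and 1 of 8 measured members was higher and 2 lower (the same adjusted over the list alone) in Treg cells, with Tox2 at 24.9 ± 3.06 CPM in Th17 cells and 0.537 ± 0.374 CPM in Treg cells. In the Th2 list, 4 of 6 measured members were higher and 1 lower (the same adjusted over the list alone) in Th17 against naive cells (median log2 fold change 4.04, or 3.82 with members at 0 counts in a group set to their bound; camera adjusted p = 0.0526, and adjusted p = 0.448 with an estimated correlation), and Il9, a Th2-associated cytokine gene, had 0 counts in the naive and Treg libraries. Among chemokine and homing receptors, 6 of 15 measured members were higher and 7 lower (the same adjusted over the list alone) in Th17 and 3 of 15 measured members were higher and 9 lower (4 and 9 adjusted over the list alone) in Treg against naive cells. The gut homing receptor gene Gpr15 reached 167 ± 21.8 CPM in Th17 cells, and Ccr9, another gut homing receptor gene, 141 and 98.9 CPM in the Treg libraries. In fatty acid oxidation, 8 of 18 measured members were higher and 1 lower (the same adjusted over the list alone) in Treg against naive cells, with Cpt1a, which carries fatty acids into mitochondria, at 1.38 ± 0.19, and 6 of 18 measured members were higher and 3 lower (the same adjusted over the list alone) in Th17 cells. In the TGF-beta response list, 10 of 17 measured members were higher and 5 lower (the same adjusted over the list alone) in Th17 against naive cells. No list of this paragraph passed camera in these comparisons (adjusted p = 0.0526 to 0.988).

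Among CD8 T cell markers, 2 of 8 measured members were higher and 4 lower (the same adjusted over the list alone) in Treg against naive cells, with Nkg7 (2.67 ± 0.28) and Cd8a (1.74 ± 0.32) higher. In Th17 against naive cells, 1 of 8 measured members was higher and 4 lower (the same adjusted over the list alone). Among immature thymocyte markers, 5 of 10 measured members were higher and 5 lower (the same adjusted over the list alone) in Treg and 2 of 10 measured members were higher and 5 lower (the same adjusted over the list alone) in Th17 against naive cells; Sox4 rose in Treg cells (3.12 ± 0.21) and Dntt fell (-5.42 ± 0.71). Rag1, a recombinase gene, was at 2.32 ± 0.117 CPM in Treg cells and 0 counts in naive libraries. Among thymic epithelial and stromal markers, 2 of 7 measured members were higher and 3 lower (the same adjusted over the list alone) in Treg and 2 of 7 measured members were higher and 2 lower (2 and 3 adjusted over the list alone) in Th17 against naive cells, with Epcam higher in Treg cells (4.49 ± 0.36). Among red cell markers, 2 of 4 measured members were higher and 0 lower (the same adjusted over the list alone) in Th17 against naive cells. Both calls, Hbb-bs and Hbb-bt, ended with DESeq2 (adjusted p = 0.277 and 0.275), with limma-voom (0.598 and 0.253) and with the replicate block (0.0524 and 0.0557). They also ended without Th17 library 1, where Hbb-bs had 140 counts, against 0 in Th17 library 5. Of the sex-linked genes only Xist was tested, at 985 ± 206 CPM, 1785 ± 342 CPM and 1389 ± 233 CPM in naive, Th17 and Treg cells. Among known long non-coding RNAs, 4 of 18 measured members were higher and 5 lower (the same adjusted over the list alone) in Th17 and 6 of 18 measured members were higher and 8 lower (the same adjusted over the list alone) in Treg against naive cells, and the imprinted RNA gene H19 was higher in Treg than in naive cells (7.14 ± 0.90). No list of this paragraph passed camera in these comparisons (adjusted p = 0.256 to 0.944), and the median and mean log2 fold changes of Treg against naive cells differ in sign for known long non-coding RNAs (-0.50 and 0.47) and immature thymocyte markers (-0.44 and 0.51).

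Ribosomal protein genes took 13.8 ± 3.02% of counts in naive, 8.72 ± 0.860% in Treg and 5.59 ± 0.548% in Th17 libraries (SD, n = 2), and 74 of 81 were lower in Th17 and 61 in Treg than in naive cells, as were 11 and 10 of 13 mitochondrially encoded genes. A bias against short genes, by the deposited gene length, was argued against as the only cause. That length need not be the length of the transcripts expressed, so a bias by transcript length was not tested. The class median log2 fold change in Th17 against naive cells was -1.62. This lay below the lowest of 1000 draws of other genes nearest in length and expression (-1.10, median length 2301 against 1770 bases, median log2 CPM 9.22 against 10.01). It also lay below the lowest of 1000 draws of genes no longer than each class member (-1.20, median length 1358, median log2 CPM 8.58). The smallest pool for these draws held 10 genes. However, the draws had lower expression than the class, and their medians lay below 0 too (-0.44 and -0.50). Over all tested genes, log2 fold changes rose with gene length (Spearman correlation 0.18 in Th17 and 0.15 in Treg against naive cells). Such a bias could therefore account for part. With scaling by total count the class median stayed at -1.37. That scaling moves all genes by about the same amount (0.24 at the median), so only the choice between it and TMM is argued against as the source. Other errors of scaling were not tested. In the ribosomal protein genes library 5 exceeded library 1 in all 3 types, by a median log2 difference of 0.59 in naive, 0.22 in Th17 and 0.22 in Treg cells. Their level thus varied between libraries of a type. Each type holds a library of each number, so a shift shared by the types does not by itself set naive cells apart. A difference in preparation between the types may add to the pattern and was not tested. A difference between the cell types, or in how they were obtained, stays open and was not tested.

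Most B cell and myeloid marker transcripts were higher in the naive libraries, Ms4a1 for example at 7.69 and 10.9 CPM in naive libraries 1 and 5, with 1 count over the Th17 and 0 over the Treg libraries, and H2-Aa at 23.3 and 32.4 CPM in naive cells. Depth is argued against, since the highest naive total count, 16569280, lies below the lowest of the other libraries (16877130). A candidate explanation is a small share of other cells in the naive libraries: of 30 further B cell and myeloid genes not in the fixed lists, 66.7% were higher in naive than in both other types, against 15.3% of all genes, and this lay between the bounds set in advance (at least 75% if other cells were the source, under 50% if not). Averages above 10 CPM in Th17 or Treg cells were found for 9 of these 30 genes, but for only 1 of 14 B cell markers and 2 of 18 myeloid and dendritic markers of the fixed lists, whose summed levels were, for the B cell list, 557 CPM in naive, 32.9 in Th17 and 576 in Treg cells, and 190, 190 and 12.2 for the myeloid list; Ighm made up most of the B cell sums in naive and Treg cells, and Cd74 most of the myeloid sum in Th17 cells. Expression by the naive cells themselves and other cells cannot be told apart here, and no sort or gate is given in the sources used here.

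Hspa1b, Hspa1a, Fos and Fosb were far higher in naive than in the other libraries (Hspa1b 1815 and 1672 CPM, Fos 469 and 575 CPM in naive libraries 1 and 5). Sharing of reads within the pair Hspa1a and Hspa1b leaves their sum as it is, and the summed CPM was at least 304 times higher in every naive library than in any other library; this value follows from the pattern itself, and sharing with other genes was not tested. For 13 further heat shock factor targets, the median log2 fold change against naive cells was 0.15 in Th17 and -0.09 in Treg cells. Both lay above the bound of -0.5. These values argue against a shift of this set near the size of that of Hspa1a and Hspa1b. Targets raised in Th17 or Treg cells for other reasons could mask a smaller response, so a general heat shock response is not excluded. Of 15 further genes that tissue handling is known to induce, 20% were higher in naive than in both other types. This share was under the bound of 50% and near the 15.3% among all genes, so these genes did not rise as a set in naive cells. Genes raised in Th17 or Treg cells for other reasons would lower the share, so handling of the naive cells is not excluded. A difference between the cell types, or in how they were obtained, stays open as a hypothesis and was not tested.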
